A study of Homo sapiens with 6 samples.

How the data were processed

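Poly(A) RNA-seq was analysed from 6 libraries of GLO1-knockout HEK293T cells, 3 untreated and 3 kept overnight in 0.2 mM MGO. Per the labels' protocols, column-purified total RNA (500 ng, RIN of 10) underwent poly(A) selection and library preparation with 8 cycles of PCR, and was sequenced as paired reads of 100 bases on a NovaSeq X. The deposited values are raw counts per gene symbol, 1 table per library with 56832 rows in the same order, which the authors had not normalized. Per the submitters' processing notes, the tools included Trim Galore, STAR 2.4, Picard and HTSeq 0.9.1, with genome build hg38. Their roles and settings, the annotation and whether counting used strand are not given in the sources used here, so overlapping and antisense genes and close paralogs are uncertain. Of the rows, 29 carried a date in place of a gene symbol, as spreadsheets produce. They held 0.178% to 0.242% of the counts of a library, 24 of them passed the filter and were tested, and none is named. The 4 rows whose names occur more than once were kept apart and are not named.

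Totals ranged from 19195920 to 45910040 counts, and the MGO libraries had fewer counts than the untreated ones, so values in MGO rest on fewer reads. PCR reads without molecular identifiers are not independent molecules. Each pair of libraries within a group was compared by a chi-square over genes with at least 20 counts in the pair. The statistic per degree of freedom was 7.24, 6.58 and 1.90 in untreated and 7.45, 14.8 and 3.44 in MGO, where sampling noise alone gives about 1, so no pair agreed within sampling noise. This does not show whether libraries came from separate cultures, and each was counted as a sample as the labels list it.

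The comparison used edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with filterByExpr (17415 genes kept), TMM scaling, robust glmQLFit, a two-sided glmQLFTest with no covariate (4 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM computed here, and log2 CPM used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 29 lists that had at least 5 measured members. The 10 gene groups chosen after the data were seen were adjusted separately. Library-wide shares were compared by a two-sided exact permutation test. Coordinates come from GENCODE release 29 on GRCh38, the assembly of hg38, matched by symbol for 14124 of the tested genes (81.1%).

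Groups, tests, the 30 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took GLO1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, a symbol other than a clone or LOC name and complete separation of the groups, the 5 rises and 5 falls with the smallest p, up to 4 members of each called list and up to 2 of every other list by p, and any member of the glyoxalase and H3K4 lists, of which the 8 and 12 with the smallest p were used. Some genes that the rule takes are not reported here. DDIT3, MALAT1, NEAT1 and SNHG12 were chosen after their values were seen, as were 10 further gene groups and the genes named from them in the closing section. The alternatives were RLE, upper quartile or library size as scaling, no filter on low counts, at least 1 CPM in every library, leaving out each library in turn, the replicate number as a fixed or random block, limma voom, the Wald test of DESeq2 1.42.0, edgeR without robust shrinkage, and a test against a fold of 1.5. Thinning the untreated libraries to the mean MGO total, and leaving out both libraries numbered 1, which had the highest mitochondrial share in their groups, were added after the data were seen.

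The test was tried on simulated data for this comparison. Genes were drawn at the means of the untreated libraries and the depths of the real libraries, and 15948 passed the filter. The test recovered 27 of 43 genes changed 1.25-fold, 38 of 46 changed 1.5-fold, 45 of 46 changed 2-fold and 47 of 49 changed 4-fold, with 13 false calls (7.65% of calls) and no wrong sign. Few genes were changed in the draw, whereas 83.1% of tested genes were called in the real comparison. The share of false calls therefore does not carry over to it. In a separate draw, in which 15946 genes passed the filter and 1 of 30 lists was shifted, the list test found the shifted list and called 0 of the others. Genes were drawn independently and lists at random, so this draw does not test lists whose members vary together.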

Results

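Messenger RNA was measured in HEK293T cells, a human embryonic kidney line, whose GLO1 gene had been knocked out. GLO1 encodes glyoxalase 1, the enzyme that starts the removal of methylglyoxal (MGO), a reactive dicarbonyl by-product of glycolysis that modifies proteins such as histones. The design held 3 libraries of untreated cells, numbered 1, 2 and 4, and 3 libraries of cells kept overnight in 0.2 mM MGO, numbered 1, 3 and 4. By its title, the series concerns the interplay between glycation of histone H3 and H3K4me3, a methyl mark of active promoters, and the comparison asked how the transcriptome of the knockout cells differed with and without MGO. Total counts were 45050433, 45910040 and 41002134 in untreated libraries 1, 2 and 4, and 19195920, 19243453 and 21544749 in MGO libraries 1, 3 and 4. The MGO libraries held on average 0.455 times the counts of the untreated libraries, and depth was split exactly as treatment was (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Levels are given as TMM-scaled CPM (counts brought to a common library size), as mean ± SD with n = 3 per group, and each change is relative to the rest of the library.

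The targeted gene was detected in every library. GLO1 (hg38 chromosome 6, 38675925 to 38703141, minus strand) had 2365, 2246 and 1969 counts in untreated libraries 1, 2 and 4, and 2434, 2641 and 3048 counts in MGO libraries 1, 3 and 4. Scaled for depth, GLO1 stood at 48.1 ± 2.57 CPM in untreated and 140 ± 5.30 CPM in MGO cells, a log2 fold change of 1.55 (SE 0.042, adjusted p = 6.96e-25, edgeR quasi-likelihood test). The same change was 1.23-fold in raw counts and 2.92-fold in TMM-scaled CPM, which divide each count by the library's depth and TMM factor. No wild-type library was analysed here, and counts over a whole gene do not show a small coding lesion, so these values do not check the knockout itself.

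Most of the measured transcriptome differed between MGO and untreated libraries. PPP1R15A, which brings a phosphatase to the translation factor eIF2 (chromosome 19, 48872392 to 48876057), rose from 46.3 ± 0.432 to 2100 ± 15 CPM. INSIG1, which holds the sterol sensor of the SREBP pathway in the endoplasmic reticulum (chromosome 7, 155297776 to 155310235), fell from 313 ± 2.74 to 17.4 ± 2.35 CPM. Of 17415 genes tested, 7282 were higher and 7182 lower in MGO (14464 in all, 83.1%, edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes were seen in 3456 higher and 2904 lower genes, and at least 4-fold changes in 1672 higher and 655 lower genes. All 3 MGO libraries lay on the same side of all 3 untreated libraries for 14542 genes (83.5%, where chance gives 10%). The first principal component held 93.1% of the variance, and the median SD of log2 CPM between libraries of a group was only 0.0408 in untreated and 0.0711 in MGO, so changes well under 2-fold passed the test. Against a fold of 1.5 in place of 1, 4363 genes were higher and 3942 lower.

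The largest rises among genes averaging at least 5 CPM included several non-coding RNAs. RPPH1, the RNA of ribonuclease P (chromosome 14, 20343075 to 20343407), rose from 0.364 ± 0.0651 to 71.7 ± 17.6 CPM (log2 fold change 7.59, adjusted p = 5.27e-05), and RMRP, the RNA of the related ribonuclease MRP, from 0.60 to 37.9 CPM. In MGO libraries 1, 3 and 4 RPPH1 stood at 90.8, 68.4 and 56.0 CPM and RMRP at 46.4, 37.2 and 30.1 CPM. That is also the order of the mitochondrial shares of these libraries. Among the other large rises, MIR22HG, PRR26, MIR3687-1, KCNQ1OT1 (54.7, 44.1 and 39.4 CPM), MIR6087 and, only slightly, PPP1R15A followed the same order. ANKRD1 went the other way, at 16.9, 18.3 and 23.0 CPM, and MAFF was lowest in MGO library 1. The closing section leaves weaker poly(A) selection in the MGO libraries open as a cause for small RNAs without a tail. The microRNA host gene MIR22HG rose 51.5-fold and KCNQ1OT1, a long non-coding RNA antisense to KCNQ1, 43.8-fold. Besides PPP1R15A (45.4-fold), protein-coding genes in this set included ANKRD1, an ankyrin repeat protein (0.261 to 19.4 CPM, 75.1-fold), and MAFF, a small bZIP transcription factor (1.45 to 64.2 CPM, 44.4-fold), and PRR26 had a log2 fold change of 5.49. MIR3687-1 (log2 fold change 6.50) lies in ribosomal DNA, which is present in many copies, and MIR6087 (log2 fold change 6.68) varied widely between MGO libraries, at 17.9 ± 10.5 CPM. With limma voom the adjusted p of MIR6087 was 0.055, and without both libraries numbered 1 it was 0.0546 (range over alternatives 6.26e-35 to 0.0552). The smallest p-values among rises belonged to PPP1R15A, ATF3, SNHG1, SLC3A2 and ZNF551. SNHG1, a host of small nucleolar RNAs, rose 16.6-fold from 18.3 ± 0.611 to 303 ± 10.0 CPM, and the zinc finger gene ZNF551 rose 14.5-fold from 14.4 ± 0.268 to 209 ± 7.61 CPM.

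The 10 largest falls among genes averaging at least 5 CPM were those of MGAT3, a glycosyltransferase (24.8 to 1.37 CPM), INSIG1 (log2 fold change -4.18), SMAD6, an inhibitor of BMP signalling (log2 fold change -3.74), LPCAT1, a phospholipid acyltransferase (161 to 12.5 CPM), the homeobox gene HOXA13, the growth factor BMP3 (-3.60), FAM217B (-3.59), the growth factor binding protein IGFBP5 (190 to 16.8 CPM), BAIAP2-AS1 (-3.49) and the iron exporter SLC40A1 (-3.48). KCNQ1OT1 and BAIAP2-AS1 are antisense to other genes, and whether the counting used strand is not given in the sources used here, so reads of the partner genes may be included. Genes with the smallest p-values among falls included TUBB, a beta tubulin (1912 ± 40.9 to 255 ± 5.52 CPM, 7.50-fold lower), IDH1, the cytosolic isocitrate dehydrogenase (132 to 13.9 CPM, 9.51-fold lower), CELSR2, a cadherin family receptor (126 to 18.5 CPM), and HMGA2, an architectural chromatin protein (192 to 27.6 CPM). TUBB belongs to a family of close paralogs and its reads may be shared with them.

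**Figure D1:**
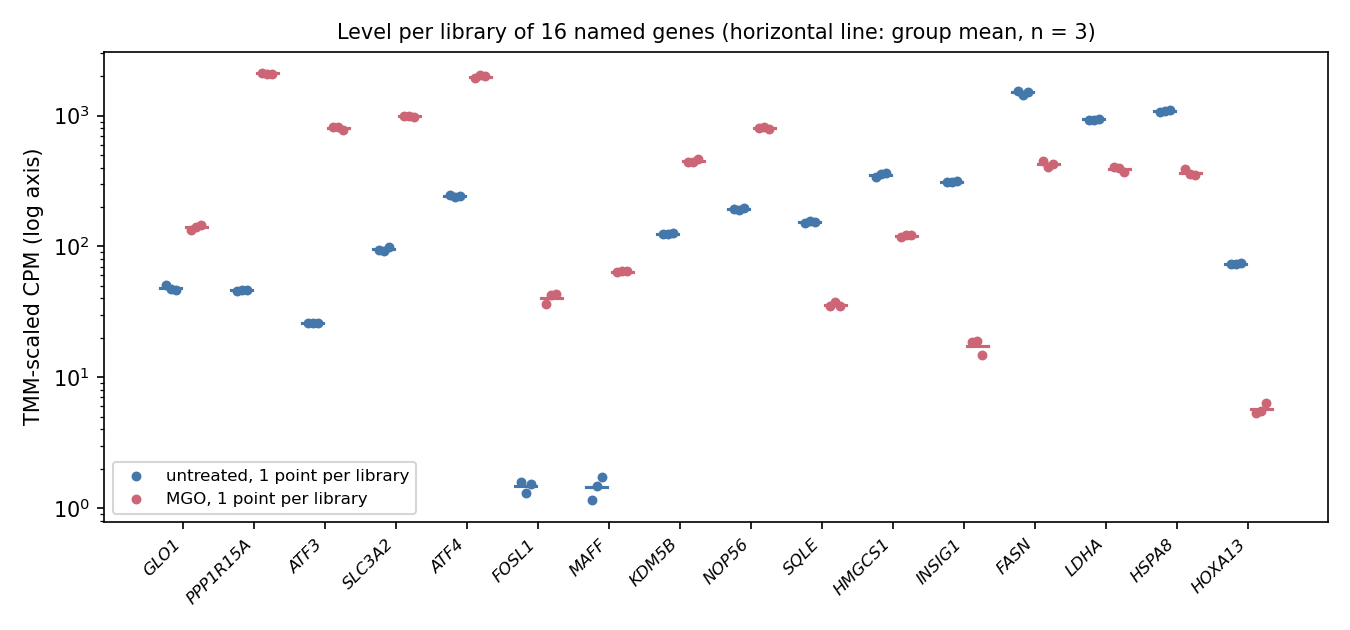
Level of 16 named genes, in TMM-scaled CPM on a logarithmic vertical axis, with 1 point for each of the 3 untreated (blue) and 3 MGO (red) libraries and a horizontal line at each group mean. PPP1R15A rose from 46.3 to 2100 CPM and INSIG1 fell from 313 to 17.4 CPM, with libraries of a group close together.

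Across 30 gene lists, 29 had at least 5 measured members and 11 of them were called by camera with a preset inter-gene correlation of 0.01, 7 toward higher and 4 toward lower expression. With a correlation estimated from these 6 libraries 0 of the 29 was called, and 4 had an unadjusted p under 0.05. That adjusted p is given beside each called list, and ranges over alternatives given for lists are those of camera, without fry. Counts of members adjusted over the list alone equalled those over all genes tested for every list except the 2 mitochondrial lists named below.

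Most measured ATF4 targets and immediate early genes rose. ATF3, a stress-induced bZIP factor, went from 26.0 ± 0.139 to 803 ± 23.9 CPM (log2 fold change 4.95, SE 0.0422, adjusted p = 9.86e-38). ATF4, the main transcription factor of the integrated stress response, went from 242 ± 4.32 to 1985 ± 55.5 CPM, and SLC3A2, the heavy chain of amino acid exchangers, from 94.6 ± 3.01 to 983 ± 3.08 CPM. Of 33 measured ATF4 targets 21 rose, 6 fell and 6 did not pass the test (adjusted p = 0.0127, and adjusted p = 0.720 with an estimated correlation). DDIT3, a stress-induced factor singled out after its values were seen, rose from 1.34 to 23.6 CPM. Among 30 immediate early genes, the first to respond to many stimuli, 22 rose, 4 fell and 4 did not pass (adjusted p = 0.000304, and adjusted p = 0.231 with an estimated correlation). Examples were FOSL1, a Fos family factor (1.47 to 40.6 CPM), ZFP36, an mRNA decay factor (8.71 to 82.2 CPM), and the Kruppel-like factor KLF6 (27.2 to 228 CPM).

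Sterol and fatty acid synthesis genes fell as groups. All 25 measured genes of cholesterol synthesis and uptake fell, 12 of them at least 2-fold, with a median log2 fold change of -0.93 (adjusted p = 6.44e-07, and adjusted p = 0.351 with an estimated correlation). SQLE, squalene epoxidase, fell from 153 ± 1.93 to 35.9 ± 1.58 CPM, MSMO1, a sterol oxidase, from 113 to 26.4 CPM, and HMGCS1, a synthase early in the pathway, from 353 ± 11.2 to 121 ± 2.45 CPM. All 13 measured fatty acid synthesis genes fell (median log2 fold change -0.71, adjusted p = 0.000304, and adjusted p = 0.386 with an estimated correlation). Among them were FASN, fatty acid synthase (1501 ± 49.8 to 425 ± 19.6 CPM), the desaturase SCD (1118 to 409 CPM), the elongase ELOVL6 (45.7 to 8.47 CPM) and ACLY, ATP citrate lyase (890 to 464 CPM). In glycolysis, the pathway that gives rise to MGO, 15 of 22 genes fell, 2 rose and 5 did not pass (median log2 fold change -0.17, adjusted p = 0.0322, and adjusted p = 0.720 with an estimated correlation). LDHA, lactate dehydrogenase, fell from 936 ± 10.2 to 390 ± 16.3 CPM and PFKP, a phosphofructokinase, from 169 to 69.4 CPM, while PGAM1 (log2 fold change -0.76) and GPI (-0.63) fell less. The call on glycolysis was lost with untreated libraries thinned to the MGO depth (adjusted p = 0.0851) and with at least 1 CPM required in every library (0.140), in a range over alternatives of 7.46e-05 to 0.720.

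Genes that write and erase H3K4 methylation went in both directions. Of 28 measured members 16 rose, 11 fell and 1 did not pass, and the list as a whole was not called (median log2 fold change 0.16, adjusted p = 0.476). The demethylase KDM5B (chromosome 1, 202724495 to 202809470), which removes H3K4me3, showed the largest rise among the 12 members named here, from 125 ± 0.631 to 449 ± 14.5 CPM (log2 fold change 1.84, SE 0.0371, adjusted p = 2.80e-28), and the related demethylase KDM5A rose from 91.7 to 185 CPM. Methyltransferase genes also rose, with KMT2C going from 29.9 to 90.7 CPM, KMT2A from 57.8 to 152 CPM and KMT2D from 130 to 227 CPM. Subunits or partners of the methyltransferase complexes were split, with NCOA6 (log2 fold change 1.28), RBBP5 (0.97) and BOD1 (0.70) higher and MEN1 (-0.89) and HCFC1 (-0.65) lower. The demethylase genes RIOX1 (-1.08) and KDM1B (-0.86) were lower.

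**Figure D2:**
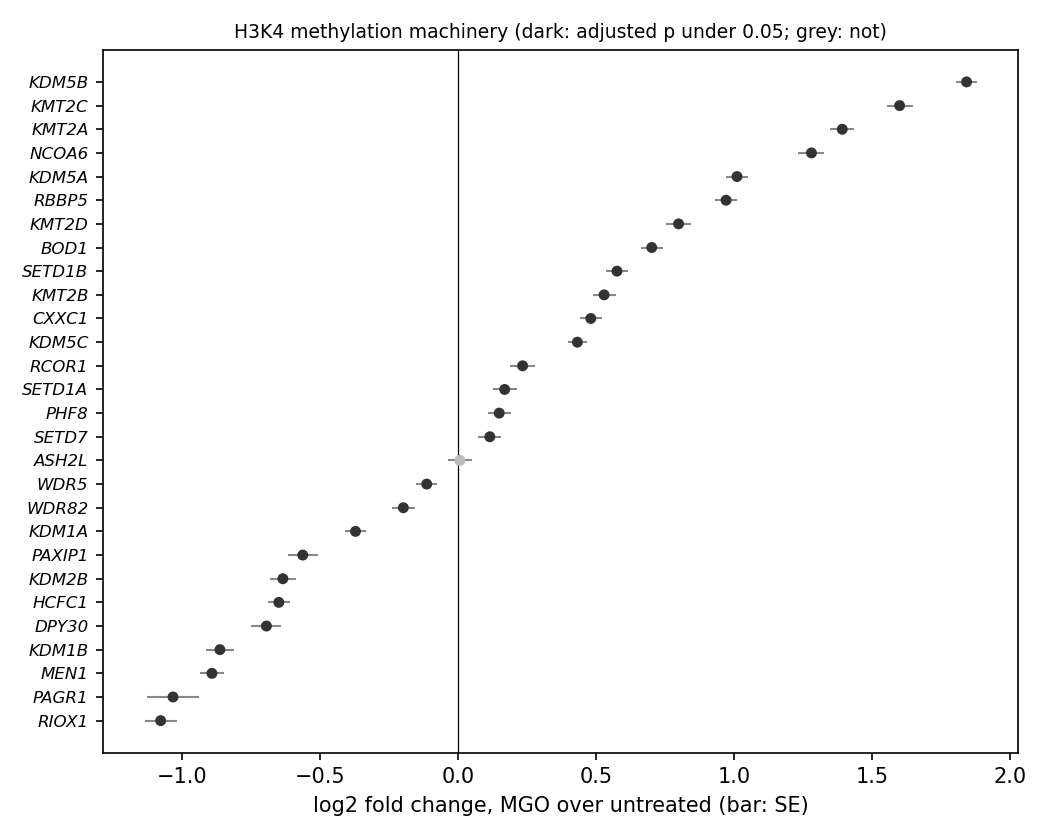
Log2 fold change of MGO against untreated, on the horizontal axis, for the 28 measured genes of the H3K4 methylation machinery, with bars of 1 SE from the edgeR fit on 3 libraries per group. KDM5B lies at 1.84 and RIOX1 at -1.08, and 16 genes rose while 11 fell.

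Genes that clear MGO and related carbonyls were mostly lower, apart from GLO1 itself. Of 17 measured members 12 fell, 1 rose (GLO1) and 4 did not pass, with a median log2 fold change of -0.26, and the list was not called (adjusted p = 0.0723). ALDH3A2, a fatty aldehyde dehydrogenase, fell from 127 ± 1.01 to 55.1 ± 2.79 CPM, ADH5, the formaldehyde-clearing dehydrogenase, from 113 to 65.4 CPM, and PARK7, a protein with reported deglycase activity, from 351 to 248 CPM. Smaller falls were seen for ESD (log2 fold change -0.48), ALDH9A1 (-0.47), GLOD4 (-0.28) and AKR7A2 (-0.26). The list passed the threshold with limma voom (0.0441), with library size as the only scaling (0.0494), with no filter on low counts (0.00218), without MGO replicate 1 (0.0166), without MGO replicate 3 (0.0457) and without both libraries numbered 1 (0.0248), in a range over alternatives of 0.00218 to 0.782.

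Developmental HOX genes fell and histone genes rose. Of 35 measured HOX genes, which pattern the body axis, 28 fell, 2 rose and 5 did not pass, and 19 fell at least 2-fold (median log2 fold change -1.02, adjusted p = 2.54e-05, and adjusted p = 0.231 with an estimated correlation). HOXA13 (chromosome 7, 27193503 to 27200106) fell from 73.5 ± 0.729 to 5.72 ± 0.533 CPM (12.8-fold, adjusted p = 1.87e-29), HOXA10 from 104 to 36.0 CPM, HOXA5 from 44.6 to 9.45 CPM and HOXC13 from 33.1 to 8.03 CPM. Of 34 measured replication-dependent histone genes 32 rose, 1 fell and 1 did not pass (median log2 fold change 2.41, adjusted p = 1.68e-06, and adjusted p = 0.231 with an estimated correlation). Their levels were low, with HIST1H2AC going from 4.45 to 35.6 CPM, HIST1H3B from 0.278 to 9.85 CPM, HIST1H4H from 2.38 to 13.1 CPM and HIST1H1E from 1.99 to 18.4 CPM. Most transcripts of these genes lack a poly(A) tail, and their coding sequences are close copies of each other, so values for single histone genes are uncertain. Weaker poly(A) selection in the MGO libraries was not tested for this list and stays open as a cause of its rise. All 10 measured small RNAs of other kinds without a poly(A) tail, a group chosen after the data were seen, also rose (median log2 fold change 5.36, or 4.83 with the member at 0 in untreated cells set to its bound at 3 counts per library).

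Genes of ribosome production and of the cell cycle tended upward. In ribosome biogenesis 27 of 34 genes rose, 5 fell and 2 did not pass (median log2 fold change 0.58, adjusted p = 0.000304, and adjusted p = 0.231 with an estimated correlation). NOP56, a core box C/D small nucleolar ribonucleoprotein, went from 192 ± 3.64 to 801 ± 10.2 CPM, UTP4 from 92.7 to 356 CPM, the RNA polymerase I factor RRN3 from 85.7 to 291 CPM and BYSL from 64.8 to 193 CPM. Of 78 cytosolic ribosomal protein genes 52 rose, 5 fell and 21 did not pass, by a median log2 fold change of 0.21 (adjusted p = 0.00737, and adjusted p = 0.868 with an estimated correlation). RPL10A rose from 647 to 1183 CPM, RPL32 from 745 to 1228 CPM and RPL12 from 545 to 775 CPM. Of 39 DNA replication genes 26 rose, 6 fell and 7 did not pass (median log2 fold change 0.28, adjusted p = 0.0127, and adjusted p = 0.720 with an estimated correlation). Those that rose included the licensing factor CDT1 (167 ± 7.01 to 683 ± 16.2 CPM), GINS3 (log2 fold change 1.34), RFC2 (0.94) and CDC6 (0.89). Of 31 mitotic genes 22 rose, 7 fell and 2 did not pass (median log2 fold change 0.36, adjusted p = 0.0127, and adjusted p = 0.720 with an estimated correlation). Rises included the kinetochore motor CENPE (11.5 to 49.7 CPM), the spindle protein TPX2 (218 to 444 CPM), NUSAP1 (153 to 305 CPM) and UBE2C (99.0 to 172 CPM). With no filter on low counts the calls on ribosomal proteins (adjusted p = 0.779), DNA replication (0.331) and mitosis (0.119) were lost, and library size as the only scaling ended the call on DNA replication (0.0606). Over the camera alternatives these values ran from 0.000429 to 0.868 for ribosomal proteins, 0.00215 to 0.720 for DNA replication and 0.00334 to 0.720 for mitosis.

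**Figure D3:**
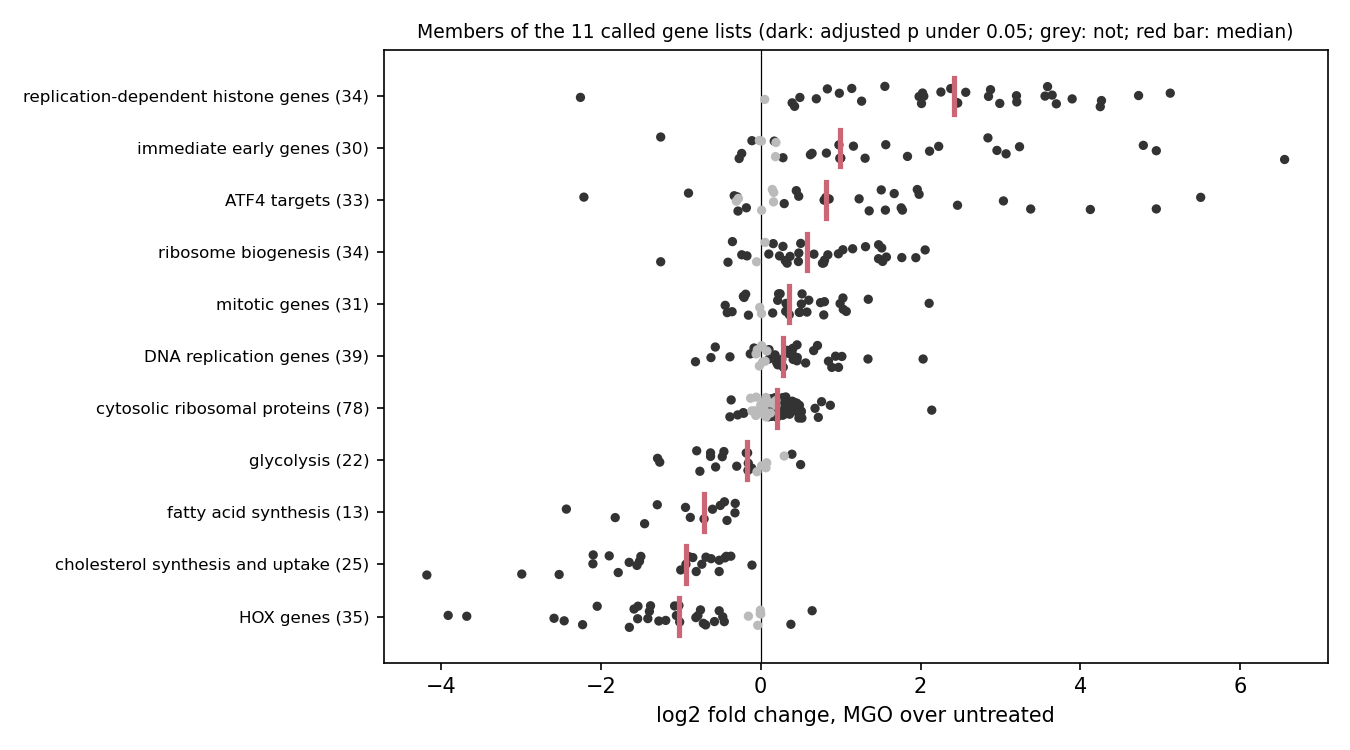
Log2 fold change of MGO against untreated for each measured member of the 11 called gene lists, 1 point per gene, with a red bar at the list's median. The medians run from -1.02 for HOX genes to 2.41 for replication-dependent histone genes.

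Other stress pathways were mixed, and none of their lists was called. Among 31 NRF2 targets 11 rose and 19 fell (adjusted p = 0.294), with the autophagy receptor SQSTM1 higher (117 to 287 CPM) and the heme transporter SLC48A1 lower (34.5 to 9.17 CPM). Of 23 HSF1 targets and chaperones 8 rose and 13 fell (adjusted p = 0.425). The constitutive chaperone HSPA8 fell from 1082 ± 26.1 to 367 ± 21.7 CPM, and the heat shock gene HSPA1A from 107 to 12 CPM, a value that is uncertain because HSPA1B is nearly identical. Of 22 genes of the endoplasmic reticulum unfolded protein response 7 rose and 11 fell (adjusted p = 0.425), with the transcription factor XBP1 higher (63.2 to 232 CPM) and the folding enzyme PDIA4 lower (325 to 127 CPM). Among 21 p53 targets 9 rose and 10 fell (adjusted p = 0.719), and GADD45A, a growth arrest gene (36.9 ± 0.956 to 296 ± 4.81 CPM), and the nuclease AEN (145 to 727 CPM) were among those that rose. DNA repair genes for bulky adducts and crosslinks rose in 16 and fell in 6 of 28 cases (adjusted p = 0.255), with ERCC6 at a log2 fold change of 0.99 and ERCC4 at 0.89. Metallothionein and metal response genes fell in 5 and rose in 2 of 7 cases (adjusted p = 0.425), the zinc importer SLC39A10 at -1.91 and the zinc exporter SLC30A1 at 0.95. With no filter on low counts 3 of these lists passed toward lower expression. They were NRF2 targets (adjusted p = 0.0159, range over alternatives 0.0159 to 0.720), HSF1 targets (0.0447, range 0.0447 to 0.868) and the unfolded protein response (0.01445, range 0.01445 to 0.720).

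Protein turnover, signalling and hypoxia lists were likewise not called. Proteasome subunits rose in 18 and fell in 10 of 31 cases (adjusted p = 0.301), with PSMC4 at a log2 fold change of 0.84 and PSMB5 at -0.93. Of 24 lysosome and autophagy genes 9 rose and 13 fell (adjusted p = 0.561), although the autophagosome genes MAP1LC3B (134 to 485 CPM) and GABARAPL1 (45.8 to 194 CPM) both rose. Aminoacyl tRNA synthetases of the cytosol rose in 9 and fell in 4 of 20 cases (adjusted p = 0.425), with YARS at 1.07 and GARS at 0.87. Hypoxia response genes rose in 7 and fell in 8 of 19 cases (adjusted p = 0.648), the histone demethylase KDM3A at 1.20 and INSIG2, a sterol-sensing relative of INSIG1, at -2.07. Of 13 NF-kB targets 4 rose and 6 fell (adjusted p = 0.719), with RELB at 1.48 and the inhibitor NFKBIA at -0.88. Of 15 YAP and TEAD targets 7 rose and 5 fell (adjusted p = 0.719), with AMOTL2 at 2.55 and CTGF at 1.98. Interferon-stimulated genes rose in 6 and fell in 11 of 17 cases (adjusted p = 0.301), among them IFIT1 (6.55 to 0.504 CPM) and OAS3 (27.1 to 12.3 CPM).

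Mitochondrially encoded transcripts made up 5.42%, 4.2% and 4.28% of counts in untreated libraries 1, 2 and 4, and 8.17%, 6.00% and 5.34% in MGO libraries 1, 3 and 4 (4.63 ± 0.680% against 6.50 ± 1.48%, n = 3 each, two-sided exact permutation p = 0.2, smallest possible 0.1). The difference of 1.87 percentage points was 1.04 without MGO replicate 1. Of 13 mitochondrially encoded subunits 1 rose, MT-ND1, and 12 did not pass, and with p-values adjusted over the list alone none passed (list adjusted p = 0.266). MT-ND1 went from 1980 ± 364 to 3794 ± 1158 CPM (adjusted p = 0.035), a call that was lost without untreated replicate 2 (0.110), untreated replicate 4 (0.109), MGO replicate 1 (0.0581) or MGO replicate 3 (0.0744). It was also lost with no filter on low counts (0.106) and against a fold of 1.5 (0.151), in a range over alternatives of 4.43e-12 to 0.151. MT-CYB stood at a log2 fold change of 0.72 (adjusted p = 0.0546). It passed with RLE scaling (0.0488), at least 1 CPM in every library (0.0377), DESeq2 (0.0181), no robust shrinkage (2.20e-05) and thinned untreated libraries (0.0472). It also passed without MGO replicate 4 (0.04885) and without both libraries numbered 1 (0.0267), in a range over alternatives of 7.53e-09 to 0.2965. Of 39 nuclear-encoded respiratory chain subunits 15 rose and 16 fell over all genes tested, or 14 and 16 adjusted over the list alone (list adjusted p = 0.671), with SDHC at -0.55. With no filter on low counts that list passed toward lower expression (adjusted p = 0.00595, range over alternatives 0.00595 to 0.916).

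Markers of other cell types were measured as a check on the samples. All 6 measured fibroblast markers fell (median log2 fold change -1.50, list adjusted p = 0.0723), including COL1A1, a collagen chain (22.8 to 11.5 CPM), and the receptor PDGFRA (3.18 to 0.429 CPM). The list passed without MGO replicate 3 (0.0421) and without MGO replicate 4 (0.0440), in a range over alternatives of 0.0307 to 0.386. Only 4 blood cell markers were measured, too few to test as a list, of which 1 rose, 1 fell and 2 did not pass, with a median log2 fold change of -0.13 and a mean of 0.32. LCP1 fell from 166 to 136 CPM, and CD74 went from 0.146 to 0.547 CPM, a call lost without both libraries numbered 1 (adjusted p = 0.0535, range over alternatives 0.000246 to 0.0535).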

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

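The test of genomic DNA and that of transcription past gene ends, given here, were set out before their results were seen. Rows that the count filter left out of the comparison held 0.142 ± 0.00753% of counts in MGO libraries, against 0.0752 ± 0.00102% in untreated libraries (n = 3 each, 1.89-fold, two-sided exact permutation p = 0.1, the smallest possible), and this signal outside the tested genes, above its level in untreated cells, is what drew attention. Genomic DNA may add reads evenly over silent genes, but long intergenic RNAs gained 3.141 times as much CPM per kb of exon as olfactory receptor genes (bootstrap interval 1.90 to 5.57), other protein-coding genes 2.38 times (1.63 to 4.08) and processed pseudogenes 10.7 times (7.07 to 18.9). These intervals lie above the even ratio of 1, which argues against evenly spread DNA as the whole cause. They do not exclude a part from DNA, and the olfactory receptor rows themselves rose from 0.00216 to 0.00500 CPM per kb of exon. The interval of the long intergenic RNAs does not clear the bound of 2 set beforehand. Olfactory receptor genes can lose shared reads to paralogs and processed pseudogenes can gain reads of their parent genes, so DNA stays open. Transcription past gene ends could add reads to silent neighbours. Silent genes here had under 1 CPM in untreated cells and at least 10 counts in all, and expressed genes at least 5 CPM in untreated cells. The silent genes were not limited to rows that the filter left out. Those starting within 10 kb downstream of an expressed gene on its strand rose more than those in the other orientation. The median log2 difference was 0.3426 (369 and 211 genes, interval 0.114 to 0.557, permutation p = 0.0016). This falls between the bounds of 0.2 and 0.5 set beforehand, so transcription past gene ends also stays open, as does a direct effect of MGO.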

How the results depend on the processing

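Thinning the untreated libraries and leaving out both libraries numbered 1 were chosen after the data were seen. The count of 14464 called genes stayed within 1.5-fold under every alternative except the test against a fold of 1.5, which called 8305 (4363 higher, 3942 lower) by its construction. Leaving out single libraries gave 13866 to 14885 calls, voom 14452, DESeq2 15265 (8050 adjusted p-values were NA), and thinned libraries 13356. Over named genes and alternatives, 2371 results were the same, 19 weaker, 8 stronger and 0 reversed, and over lists 438, 18, 27 and 9. The list counts include fry as well as camera, unlike the ranges given for lists. Of the 11 called lists, 0 passed with an estimated correlation (4 of 29 lists at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 25. GLO1 rose 2.92-fold in CPM and 1.23-fold in raw counts, which leave out both depth and the TMM factor. Lists that were not called changed direction as follows, and the cause was not tested. With no filter this held for H3K4 machinery (adjusted p = 0.8779), aminoacyl tRNA synthetases (0.6542), p53 targets (0.596), proteasome (0.6618) and YAP targets (0.9962). With at least 1 CPM it held for the respiratory chain (0.8443) and NF-kB targets (0.7091), and NF-kB targets also turned with thinned libraries (0.9964) and without both libraries numbered 1 (0.9315). Over the camera alternatives the adjusted p of these 7 lists ran from 0.00595 to 0.996. The median log2 fold change of the tested genes was 0.01, and moved to -0.10 with library size alone, where 6554 genes were higher and 7854 lower, and to -0.18 with no filter, where 12 calls had the opposite sign. The mitochondrial share differed by 1.04 to 2.45 percentage points with single libraries left out. Deviations of same-numbered libraries correlated at 0.0177 (number 1) and -0.0269 (number 4), others at -0.0289 to 0.0344. This gave no sign of pairing by replicate number, but so few pairs cannot exclude it, and the labels do not say. A replicate block gave 13451 calls as a fixed term, with 1 residual degree of freedom, and 14452 as a random effect. Under the fixed block glycolysis was not called (adjusted p = 0.07303), and fibroblast markers were (0.03074), as was MT-CYB (7.533e-09). Lists were not run under the random effect, since camera takes no block. In the shallower MGO libraries 16178 ± 115 rows had at least 10 counts, against 17009 ± 119 in the untreated ones.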

Other observations

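Gene groups in this part were chosen after the data were seen. Their p-values were adjusted over these 10 groups, apart from the 29 lists. Because the same data led to the choice, these p-values describe the groups and are not independent tests of them. Of 468 zinc finger genes named ZNF, many of them transcriptional repressors, 345 were higher and 75 lower (median log2 fold change 0.79, camera adjusted p = 1.40e-09, and adjusted p = 0.0873 with an estimated correlation). Hosts of small nucleolar RNAs were higher in 15 of 17 cases (median 2.06, adjusted p = 0.000188, and 0.261 as the adjusted p with an estimated correlation), such as SNHG12, which rose from 2.52 to 60.4 CPM, and GAS5, from 29.6 to 126 CPM. Of 11 nuclear long non-coding RNAs 10 rose and 1 fell (median 2.01, camera adjusted p = 0.00441, and 0.15 as the adjusted p with an estimated correlation). Those that rose included MALAT1 (21.9 ± 2.95 to 259 ± 25.7 CPM) and NEAT1 (25.5 ± 4.03 to 191 ± 21.4 CPM), both residents of nuclear bodies. In MGO libraries 1, 3 and 4 MALAT1 stood at 279, 267 and 230 CPM and NEAT1 at 213, 191 and 170 CPM, in the order seen for RPPH1. Weaker poly(A) selection in the MGO libraries was not tested for this group and stays open. All 10 measured small RNAs without a poly(A) tail rose, with a median of 5.36, or 4.83 with the member at 0 in untreated cells set to its bound at 3 counts per library (adjusted p = 0.000636, and 0.15 as the adjusted p with an estimated correlation).

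Most measured solute carrier and protocadherin genes fell. Of 262 solute carrier genes 158 fell and 64 rose (median log2 fold change -0.39, camera adjusted p = 0.00151, and 0.0873 as the adjusted p with an estimated correlation), and of 30 protocadherin genes, whose clustered members share exons, 20 fell and 7 rose (median -1.07, mean -0.40, adjusted p = 0.0332, and 0.15 as the adjusted p with an estimated correlation). Not called were collagens (20 of 33 lower, 11 higher, median -0.77, adjusted p = 0.139), olfactory receptors (4 of 7 higher, adjusted p = 0.139), abundant housekeeping mRNAs (3 of 14 higher, 7 lower, adjusted p = 0.299) and mitochondrial ribosomal proteins (38 of 77 higher, 28 lower, adjusted p = 0.385). Among protein-coding genes the median log2 fold change was 0.01 in the tenth with the shortest spans (median 3.52 kb) and -0.44 in the longest (279 kb), a Spearman correlation across genes of -0.143, where genes are not independent replicates. Transcribed unprocessed pseudogenes were higher in 72 of 91 cases and lower in 8.

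The tests of genomic DNA and of poly(A) selection in this paragraph were chosen after the result was seen. The test of depth was set out before its own result was seen, but thinning and the ZNF group were both chosen after the data were seen. Olfactory receptor genes rose by 0.6228% of the median ZNF rise in CPM per kb of exon, which argues against genomic DNA as the cause of the ZNF rise. The ZNF median stayed at 0.8218 with untreated libraries thinned to the MGO depth. Random thinning keeps the expected share of each gene, so this test could not decide on depth or on what went along with it. Weaker poly(A) selection may raise RNAs without tails or with short ones, and it stays open for ZNF mRNAs, which lay 0.8913 above other protein-coding genes (bootstrap interval 0.803 to 1.01), since tail lengths were not measured and that difference restates the pattern. For the small RNAs it stays open too. Their log2 fold changes had an SD of 2.465, above the bound set for a common loss of selection. That bound was set after the result was seen, and the spread that such a loss gives was not measured, so the SD decides nothing. All 10 rose, and the selection of each library cannot be told apart from treatment. A response of ZNF mRNAs to MGO itself stays among the open explanations, untested.

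The fall of HOX genes was tested in ways set out beforehand. After the trend of fold change over length, exon number and GC was removed, which held 7.35% of the variance among protein-coding genes, the HOX median was -1.1 (interval -1.40 to -0.601, from -1.02 before), and under the scaling that brought it nearest to 0 it was -0.9999. The first value argues against length, exon number and GC as the whole cause. The scalings moved the median of all tested genes only between -0.10 and 0.03. They could not bring the HOX median near 0, so the second value shows only that the fall did not hang on the scaling chosen. A response to MGO itself was not tested.

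The 6 libraries can be split 3 against 3 in 10 ways, and 1 of them, the real one, called as many as 14464 genes. The highest of the others called 0 with edgeR (5 to 21 genes at an unadjusted p under 0.05, no other tool was run), and with 10 splits no share under 0.05 can be had.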
